A study of Mus musculus with 2 samples.

How the data were processed

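Single-cell RNA sequencing was performed on CD8+ T cells of OT-I mice, which carry a transgenic T cell receptor for an ovalbumin peptide (SIINFEKL). Per the labels' protocols, spleen and lymph node cells were activated with the peptide for 48 h in medium with 100 U/ml interleukin-2 and then kept for 20 h under control conditions (11 mM glucose) or transient glucose restriction (TGR, 1 mM glucose). The sample descriptions instead name 3 days of growth before the acute exposure. Neither source says whether the cells were given full glucose again before they were captured. There was 1 library per condition, made with the 10x Chromium platform (v2 chemistry) and sequenced on a HiSeq 3000, per the labels.

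The deposited matrices hold whole-number counts of unique molecular identifiers (UMIs) per gene and cell barcode, with no normalization. Cell Ranger 2.2, Seurat 3 and the mm10 genome build are named in the submitters' processing notes, which as used here do not say which step each tool served or whether barcodes were filtered. The lowest number of genes per deposited barcode was 520 in the control library and 530 in the TGR library. The labels state that about 5000 cells were loaded per channel and that 3000 were recovered on average, and the files hold 3336 control and 2548 TGR barcodes. Both files list the same 27998 genes, of which 14990 had a UMI in the cells kept. Gene coordinates were taken from GENCODE M21 (GRCm38, the assembly also called mm10) by Ensembl identifier, and 27645 identifiers matched.

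A barcode was kept when it had at least 500 genes and under 10% of its UMIs on mitochondrially encoded genes. This left 3127 control and 2546 TGR cells with 14730128 and 19696068 UMIs. All 209 control and 2 TGR barcodes removed exceeded the mitochondrial limit. Doublets were called with Scrublet through scanpy 1.11.5 and left in. It called 11 of 3336 control and 4 of 2548 TGR barcodes, which is too few for the number of cells, so doublets remain in effect untested.

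UMIs were summed over the kept cells of each library and scaled to CPM (counts per 10⁶) of that sum. The log2 ratio of TGR over control was computed with 0.5 UMI added per library, scaled by library size. Its 95% interval came from the exact Clopper-Pearson interval of the gene's split of UMIs between the libraries. Such intervals, and the exact binomial intervals of shares, cover counting error only. With 1 library per condition no test of the conditions could be run, no p-value is given, and every difference has no replicate check and describes 2 libraries. A gene was scored with at least 10 CPM in either library. Genes at least 2-fold higher or lower were counted when the interval excluded a ratio of 1. A list member was counted as higher or lower at 1.5-fold under the same condition.

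Before the data were examined, 36 gene lists, the rule for named genes and the markers of cell types were fixed. The median log2 ratio of each list was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. Percentiles above 97.5 or below 2.5 are called above or below the random lists, as a description of these libraries. Lists with fewer than 4 scored members have no percentile. Some genes are members of several lists, so lists that share them are not independent of each other. The named genes are the 12 with the highest and the 12 with the lowest ratio among those with at least 25 CPM in either library, passing over predicted genes, receptor segments and pseudogenes. To these were added, from each list, the 2 scored members with the largest absolute log2 ratio and the 2 with the highest mean CPM. A fixed set of glucose response, effector and memory genes was added too. Some genes that met the rule are not reported here. Genes outside the rule that are named because a count was 5 or smaller were chosen after their values were seen.

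Cells were assigned to cell cycle phases after each was thinned to 1500 UMIs, which left out 91 control cells and 0 TGR cells as too shallow. Clusters were made from both libraries together (Leiden, resolution 0.5, 2000 variable genes, 30 components, 15 neighbours, no integration). A marker counted as detected with a UMI in at least 10% of a cluster, and as enriched if it also had at least 50 CPM and at least 2-fold the level of the other cells, with 5 CPM added to both. A cluster with fewer than 3 enriched markers of any other class was called CD8 T-like when at least 3 CD8 T cell markers were detected. A cluster with 3 or more enriched markers of another class was given that class, unless at least as many CD8 T cell markers were detected, in which case it stayed unnamed. This last exception was added after the clusters were seen. Ratios were recomputed within the 3 phases and within 3 bands of UMIs per cell.

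The alternatives were edgeR 4.0.16 TMM factors, DESeq2 1.42.0 size factors, totals without ribosomal protein and mitochondrial genes, no filter on low values, a minimum of 50 CPM, all deposited barcodes, a filter of 1000 genes and 5% mitochondrial UMIs, removal of called doublets, equal weight per cell, CD8 T-like clusters only, and thinned cells. The calculation was tested on 2 simulated libraries with 6445 scored genes and 200 changed genes. It called 98 of 100 genes changed 2.5-fold and 98 of 100 changed 4-fold, with 0 unchanged genes called and intervals covering the true ratio for 95.1% of genes. Counts were independent Poisson draws, so coverage near 95% was fixed by the setting. Clustering of UMIs by cell and variation between cultures were not simulated. A list shifted by 0.4 log2 units stood at percentile 100, and 2 of 34 unchanged lists passed a limit. All other genes were unchanged there, unlike in the data, so recovery in the real libraries was not measured. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and R 4.3.3. Counts of ribosomal protein, histone and other multicopy genes are uncertain where reads match near-identical copies. Whether the counting used strand is not given in the sources used here, so overlapping antisense genes are also uncertain.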

Results

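Effector CD8+ T cells from OT-I mice were profiled by single-cell RNA sequencing after culture in 11 mM glucose (control) or after 20 h of transient glucose restriction in 1 mM glucose (TGR), with 1 library each. The series concerns metabolic conditioning of such cells before adoptive transfer. The control library held 3336 barcodes and 15103830 UMIs and the TGR library 2548 barcodes and 19702050 UMIs. After filtering, 3127 control cells had a median of 4030 UMIs and 1385 genes, and 2546 TGR cells a median of 6266 UMIs and 1676 genes. TGR cells thus had more UMIs each, and whether this came from RNA content, capture or sequencing could not be told. The median share of UMIs on mitochondrially encoded genes was 2.74% in control and 2.49% in TGR cells. Ribosomal protein genes took a median of 39.2% of UMIs in control cells and 49.0% in TGR cells. This larger share lowers the CPM of other genes in the TGR library and applies to each gene group that follows. There are no replicates, so no value has an error between cultures.

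The first question was which transcripts differed most between the libraries. Among genes with at least 25 CPM in either library, those highest in the TGR library relative to control included several stress response genes, and those lowest included linker histone and tubulin genes. Ddit3, which encodes the stress transcription factor CHOP, was at 12.6 CPM in control and 267 CPM in TGR, 21.2-fold higher with a counting interval of 18.4 to 24.7. Atf5, another stress transcription factor, was at 5.02 and 90.8 CPM, 18.0-fold higher (interval 14.3 to 23.1). Cox6a2, a subunit isoform of cytochrome c oxidase typical of muscle, had 2 UMIs in control and 1266 in TGR, a ratio of 390 with an interval of 131 to 3913. Angptl6 (5.43 and 56.6 CPM), the small nucleolar RNA host genes Snhg12 (45.2 and 448 CPM) and Snhg6 (49.6 and 426 CPM) and the pseudokinase gene Trib3 (15.8 and 136 CPM) were also 8.56-fold to 10.4-fold higher. Fam129a, Mt2 (a metallothionein), Cd7, Pck2 (mitochondrial phosphoenolpyruvate carboxykinase) and Bbc3 (the pro-apoptotic protein PUMA) completed the highest 12, with ratios from 6.70 down to 4.45. Within cells called G1 the ratio was 3.47 for Fam129a and 2.22 for Bbc3.

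Among genes lower in the TGR library, the interferon-inducible Ifitm1 was at 53.8 CPM in control and 4.77 CPM in TGR, 11.2-fold lower (interval 9.10 to 14.1). Its log2 ratio was −3.49, and −3.16 in CD8 T-like clusters only. It was 5.33-fold lower within cells called G1, 33.2-fold within S (103 and 3 UMIs) and 18.7-fold within G2/M. Tuba4a, an alpha-tubulin, was 7.87-fold lower and Tfrc, the transferrin receptor that takes up iron, was 6.45-fold lower (136 and 21.1 CPM, interval 5.81 to 7.19). Linker histone genes Hist1h1a, Hist1h1b and Hist1h1d were 6.78-fold, 5.05-fold and 4.85-fold lower. The mitotic cyclin gene Ccnb1 was at 66.3 and 11.7 CPM. Tmem97, Dbi, Tuba1c and Srsf7 were between 6.14-fold and 4.74-fold lower.

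**Figure D1:**
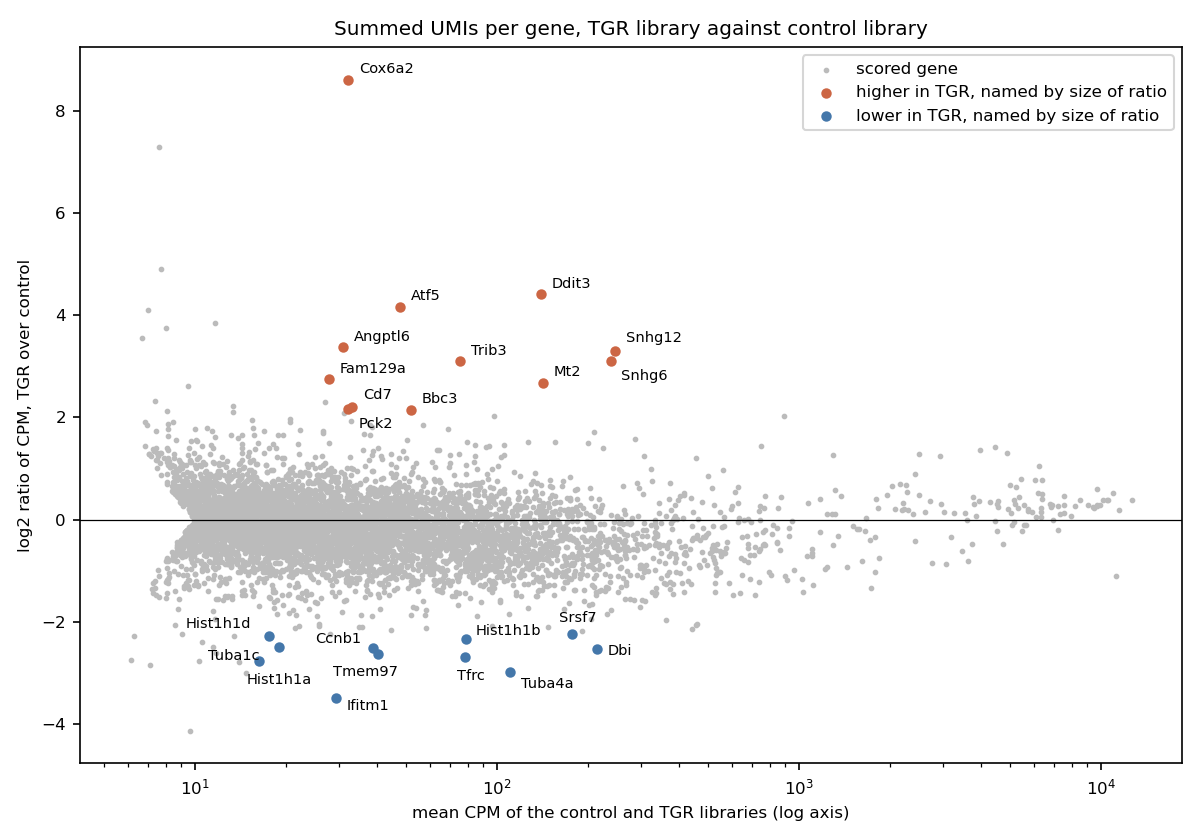
Each point is a scored gene, with its mean CPM over both libraries on a log x axis and its log2 ratio of TGR over control on the y axis. Coloured points are named genes with the highest and lowest ratios among those with at least 25 CPM in either library, from Cox6a2 at 8.61 to Ifitm1 at −3.49.

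Of 6667 scored genes, 221 were at least 2-fold higher and 525 at least 2-fold lower in the TGR library, with a median log2 ratio of −0.16. Higher genes were thus 29.6% of those counted. With ribosomal protein and mitochondrial genes left out of the totals, 405 were higher and 235 lower (63.3% higher), and the median was 0.10. That scaling raises every log2 ratio by 0.26, so a negative ratio closer to 0 than this turns positive under it. Ratios below are on the total UMI scale and are best read against the median of −0.16. At 1.5-fold, the limit for list members, 568 of 6552 scored protein-coding genes were higher and 1448 lower. Counts of members below are best read against these numbers.

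Ddit3 and Atf5 lie at these positions in the mouse genome (GRCm38): chromosome 10 from 127290774 to 127296288 on the plus strand (Ddit3, ENSMUSG00000025408) and chromosome 7 from 44812256 to 44816658 on the minus strand (Atf5, ENSMUSG00000038539). Cox6a2 (ENSMUSG00000030785) lies on chromosome 7 from 128205435 to 128206387 on the minus strand, inside the span of the oppositely oriented Itgad, which had 1 UMI in control and 0 in TGR. Tfrc (ENSMUSG00000022797) lies on chromosome 16 from 32608920 to 32632794.

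Stress responses were examined by list. Among targets of ATF4, the transcription factor of the amino acid response, 14 of 20 measured members were higher and 0 lower in the TGR library. Their median log2 ratio of 0.83 stood at percentile 100 of the random lists. Atf4 itself was at 105 and 297 CPM, and Asns, the asparagine synthetase gene, at 8.62 and 32.6 CPM. Phgdh, which opens serine synthesis, did not share this direction at 256 and 229 CPM. Endoplasmic reticulum chaperones and unfolded protein response genes lay within the random lists (median 0.0077, percentile 97.1), with 3 of 22 higher (Hspa5, Herpud1 and Sel1l) and 1 lower (Ssr1). Hspa5, the chaperone BiP, was at 98.5 and 166 CPM, and Herpud1 at 25.5 and 57.7 CPM. Among p53 targets 8 of 14 were higher and 1 lower, with a median of 0.61 at percentile 99.99. The cell cycle inhibitor gene Cdkn1a was at 25.9 and 63.4 CPM, whereas Rps27l was at 1418 and 634 CPM, and through such abundant members the summed CPM of the list was lower in TGR (2085 and 1418 CPM). Within cells called G1, Cdkn1a was at 55.0 and 50.1 CPM and the list lay within the random lists (median 0.070, percentile 90.9).

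Of the other stress lists, only that of autophagy and lysosome genes stood above the random lists over all kept cells. Heat shock genes had a median of −0.36 (percentile 40.5), with 1 of 14 higher and 4 lower (Hspd1, Hsph1, Hsp90aa1 and Dnaja1). The higher member, Hspa1a, had 1 UMI in control and 299 in TGR, a ratio of 157 with an interval of 39.8 to 8861, but only 2.12% of TGR cells held a UMI of it. Hsp90aa1 was at 605 and 227 CPM. NRF2 and antioxidant genes had a median of −0.10 (percentile 76.4). Their 5 higher members were Hmox1 (1.02 and 12.3 CPM), Sqstm1 (18.3 and 57.5 CPM), Ftl1, Gclc and Gclm, and their 4 lower members Prdx1, Txn1, Sod2 and Gpx1. Targets of the hypoxia factor HIF1 outside glycolysis had a median of 0.18 (percentile 96.8), with Bnip3l and Bhlhe40 higher and Egln3 lower among 13. Autophagy and lysosome genes stood above the random lists (median 0.30, percentile 99.9). Of 20 measured, 5 were higher (Map1lc3a, Gabarapl1, Atg12, Lamp2 and Npc2) and 2 lower (Gabarapl2 and Ctsz), and with a minimum of 50 CPM the median was −0.018. Within cells called G1 (median 0.0034, percentile 87.1) and in the lowest UMI band (median 0.15, percentile 94.4) the list lay within the random lists.

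The next question was how genes of glucose handling compared. Glycolysis and glucose or lactate transport genes went both ways and as a list lay within the random lists (median −0.20, percentile 49.4). Of 18 measured, 4 were higher: Pgk1 (22.1 and 58.4 CPM), Aldoa (767 and 1834 CPM), Aldoc and Gpi1. Another 7 were lower, among them the lactate exporter gene Slc16a3, 4.28-fold lower at 57.9 and 13.5 CPM, and the glucose transporter gene Slc2a1, at 29.1 and 14.2 CPM. Slc2a3, a second glucose transporter gene, was at 33.2 and 45.8 CPM, Hk2 at 22.5 and 15.3 CPM and Gapdh at 1862 and 2695 CPM. Txnip, whose transcription is known to follow glucose through MondoA, was 2.29-fold lower at 51.6 and 22.5 CPM. It was the only scored member of its list of 6. Arrdc4, another such target, had 31 and 18 UMIs. In the pentose phosphate pathway 0 of 9 were higher and 3 lower (Pgd, Prps1 and Taldo1), with a median of −0.42 (percentile 14.8). Prps1 was at 16.6 and 16.1 CPM within cells called G1. Hexosamine and O-GlcNAc genes stood above the random lists (median 0.53, percentile 99.8). The O-GlcNAc transferase gene Ogt (85.1 and 154 CPM) and Nagk (8.62 and 14.6 CPM) were the 2 higher members of 7.

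Among nuclear-encoded mitochondrial genes, the lists for oxidative phosphorylation and the TCA cycle stood below the random lists, and fatty acid oxidation did not. In oxidative phosphorylation 47 of 73 were lower and 3 higher (Atp5sl, Ndufa6 and Cox7a2l), with a median of −0.79 at percentile 0. Ndufa4 was at 578 and 149 CPM and the ATP synthase subunit gene Atp5g3 at 457 and 140 CPM. In the TCA cycle 9 of 22 were lower and 0 higher (median −0.51, percentile 1.15), including Sdhb (235 and 100 CPM). Messages of the mitochondrial genome lay within the random lists (median −0.22, percentile 52.9), with mt-Nd1, mt-Nd2 and mt-Nd6 lower among 13. Fatty acid oxidation genes did too (median −0.064, percentile 59.7), with Etfdh higher and Acaa2 and Etfb lower among 16.

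Lipid synthesis genes were lower as groups. Of 21 measured genes of cholesterol synthesis, targets of SREBP2, 18 were lower and 0 higher, with a median of −1.28 at percentile 0. Fdps, which makes farnesyl diphosphate, was at 80.4 and 24.7 CPM. In fatty acid synthesis 7 of 11 were lower and 0 higher (median −0.90, percentile 0.01). Scd1, a stearoyl-CoA desaturase gene, was 17.5-fold lower with 269 and 20 UMIs (interval 11.4 to 29.9), and the fatty acid synthase gene Fasn was 3.31-fold lower at 83.1 and 25.1 CPM.

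**Figure D2:**
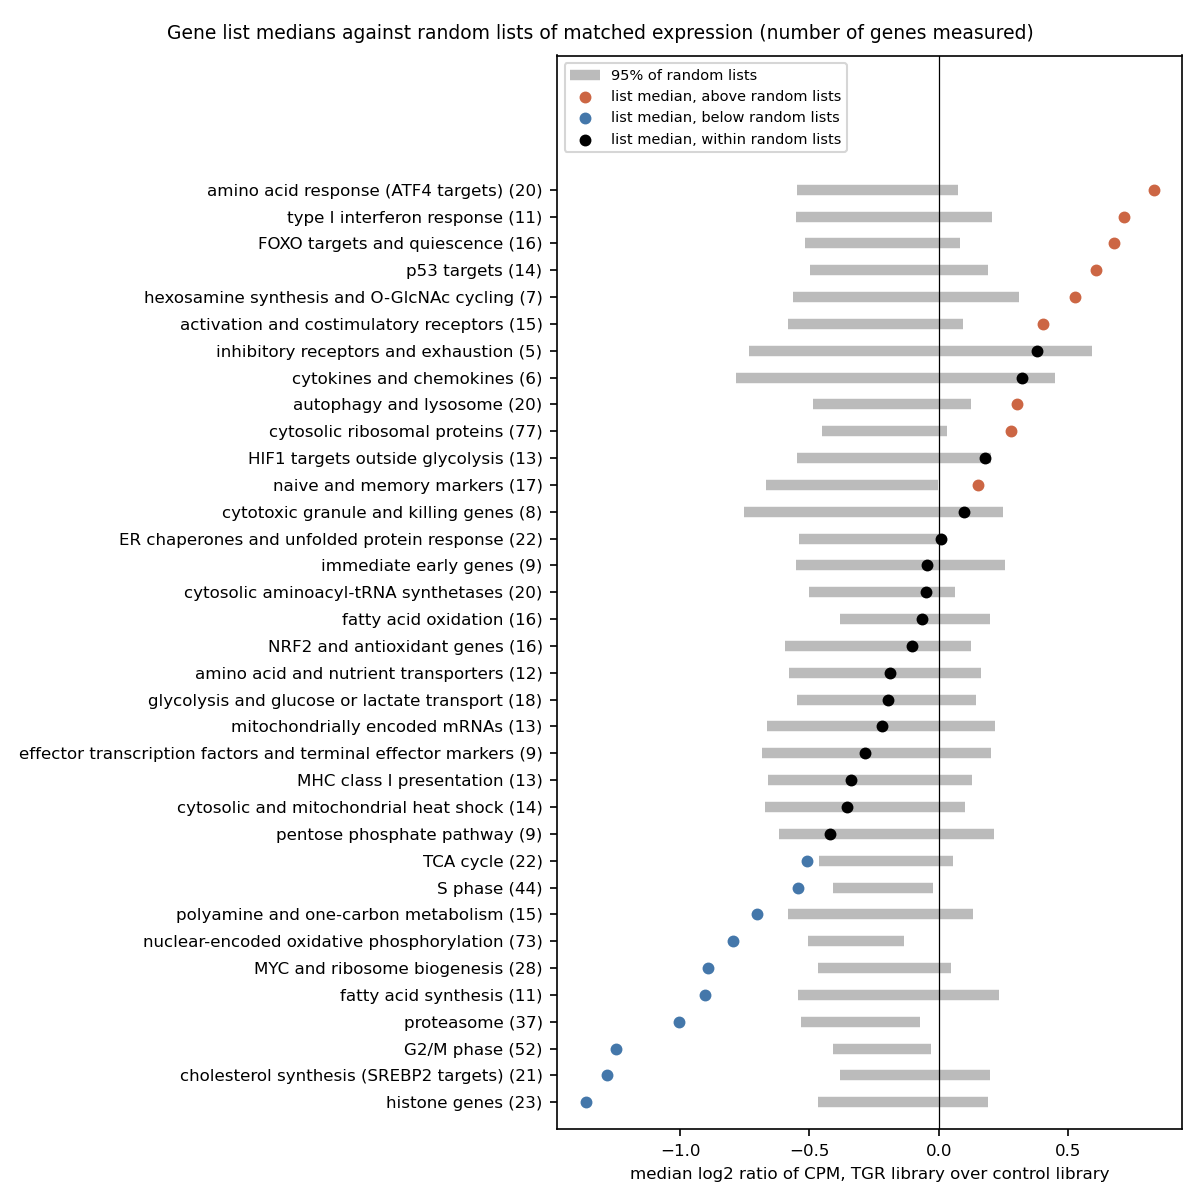
Points give the median log2 ratio of TGR over control for each gene list, with the number of genes measured in brackets, and grey bars the central 95% of 10000 random lists of matched expression. Of the 35 lists with a percentile, 9 stood above and 10 below the random lists, from ATF4 targets at 0.83 to histone genes at −1.37.

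Genes of growth and protein turnover showed both directions. MYC and ribosome biogenesis genes were lower in 18 of 28 cases and higher in 0 (median −0.89, percentile 0), including Bop1 (27.9 and 9.34 CPM) and Cad (26.3 and 9.09 CPM). Within cells called G1 the list lay within the random lists (median −0.40, percentile 3.47), with Bop1 at 13.5 and 10.1 CPM, as it did in the lowest UMI band (median −0.26, percentile 21.6). Myc itself was at 34.7 and 28.8 CPM, and the abundant members Npm1 and Ncl were at 2635 and 3257 CPM and at 979 and 717 CPM. Cytosolic ribosomal protein messages stood above the random lists (median 0.28, percentile 100), with 12 of 77 higher and 0 lower. Rps27 was at 2416 and 6506 CPM and Rps29 at 2808 and 6960 CPM. Proteasome genes were lower in 31 of 37 cases and higher in 0 (median −1.004, percentile 0), and Psmb2 was at 315 and 99.8 CPM. Polyamine and one-carbon genes had a median of −0.70 (percentile 0.6). Of 15, 8 were lower and 3 higher (Sat1, and Shmt2 and Mthfd2, which the ATF4 target list also holds). Odc1, which starts polyamine synthesis, was at 239 and 103 CPM, and Sat1, which acetylates polyamines, at 25.7 and 75.3 CPM. Within subsets of cells this list stood below the random lists in 0 of 6. Cytosolic aminoacyl-tRNA synthetase genes lay within the random lists (median −0.048, percentile 87.4), with Sars and Cars higher and Farsa, Hars, Kars and Rars lower among 20. Amino acid and nutrient transporter genes did too (median −0.19, percentile 53.2), with Slc3a2 (64.8 and 121 CPM) and Slc7a5 higher and Slc19a1 lower among 12.

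The G2/M, S phase and histone lists stood below the random lists. Among G2/M genes 44 of 52 were lower and 1 higher (Psrc1), with a median of −1.25 at percentile 0, and Cenpf was at 240 and 56.2 CPM and Cdc20 at 72.9 and 16.3 CPM. Within cells called G2/M, a call that itself uses such genes, Cenpf was 2.56-fold and Cdc20 2.63-fold lower. Among S phase genes 21 of 44 were lower and 0 higher (median −0.54, percentile 0.11). Histone genes were lower in 20 of 23 cases and higher in 0 (median −1.37, percentile 0). Most histone messages carry no poly(A) tail, and capture by poly(A) samples them unevenly. After thinning, phase calls placed 2784 of 3036 control cells (91.7%, exact interval 90.7 to 92.7) and 1207 of 2546 TGR cells (47.4%, 45.5 to 49.4) in S or G2/M. The unthinned shares were 95.01% and 50.1%. Phase calls rest on relative scores, and RNA free in the droplets was not estimated, so no rate of division is read from them. FOXO target and quiescence genes stood above the random lists, with 9 of 16 higher and 0 lower (median 0.68, percentile 100). The anti-proliferative gene Btg1 was at 98.0 and 323 CPM, Pik3ip1 at 31.2 and 107 CPM and Tsc22d3 at 11.8 and 50.5 CPM. Btg1 was at 180 and 357 CPM within cells called G1.

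**Figure D3:**
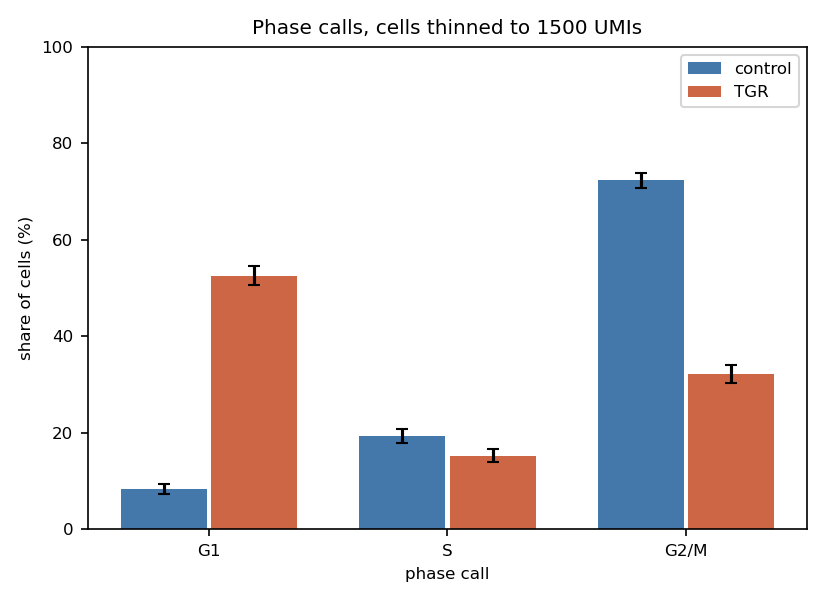
Bars give the share of cells (%) called G1, S or G2/M in the control and TGR libraries after thinning to 1500 UMIs per cell, with 95% exact binomial intervals for counting error only. G2/M calls made up 72.4% of control and 32.2% of TGR cells, and G1 calls 8.30% and 52.6%.

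The last question concerned genes of T cell function. Cytotoxic genes were mixed and lay within the random lists (median 0.10, percentile 91.0), with 0 of 8 higher and 2 lower. The lower members were the most abundant: Gzmb (granzyme B) at 803 and 480 CPM, 1.67-fold lower with an interval of 1.63 to 1.72, and Nkg7 at 867 and 488 CPM. Gzmb was at 711 and 590 CPM within cells called G1. Prf1 (perforin) had 2 and 11 UMIs, too few to separate (ratio 3.56, interval 0.898 to 38.2). Among 6 cytokine and chemokine genes (median 0.32, percentile 94.0) Ccl5 (61.6 and 145 CPM) and Xcl1 (3.94 and 12.3 CPM) were higher and Tnf lower. Within cells called G1, Ccl5 was closer between the libraries, at 132 and 163 CPM. Ifng was below the scoring limit with 15 and 46 UMIs.

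Activation and costimulatory receptor genes stood above the random lists (median 0.40, percentile 99.99). Of 15 measured, 4 were higher (Cd200, Tnfrsf9, Cd69 and Tnfrsf4) and 1 lower (Tfrc), and Il2ra, the high affinity interleukin-2 receptor chain, was at 189 and 129 CPM. Naive and memory markers had a median of 0.15 (percentile 99.7) but a mean of −0.0078. Here 5 of 17 were higher (Il7r, S1pr1, Klf2, Lef1 and Bach2) and 4 lower (Eomes, Id3, Dapl1 and Igfbp4). Of these, Il7r, S1pr1 and Klf2 also belong to the FOXO target list. Il7r, the interleukin-7 receptor, was at 34.6 and 70.6 CPM, but at 63.3 and 64.9 CPM within cells called G1. The median of the naive and memory list within G1 was −0.075. Tcf7 (TCF1) was at 166 and 198 CPM. Inhibitory receptor genes lay within the random lists (median 0.38, percentile 89.9, 5 measured), with Lag3 (17.0 and 34.7 CPM) and Tox higher and Cd160 and Btla lower. Pdcd1 (PD-1) was at 3.39 and 3.40 CPM.

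Effector transcription factor and terminal effector genes had a median of −0.28 (percentile 40.3), with Bhlhe40 higher and Irf8, Batf3 and Id2 lower among 9. Type I interferon response genes stood above the random lists with 6 of 11 higher and 0 lower (median 0.72, percentile 100), including Rtp4 (10.2 and 26.9 CPM) and Xaf1 (12.8 and 31.4 CPM). With a minimum of 50 CPM that median was −0.049, since abundant members such as Ifi27l2a (827 and 720 CPM) were not higher. With the TGR library clustered alone, Rtp4, Isg15, Xaf1 and Zbp1 were among the leading genes of a cluster of 465 cells. These genes were thus uneven among TGR cells, and how much of the list's difference that cluster carried was not measured. MHC class I presentation genes lay within the random lists (median −0.34, percentile 37.6). Of 13, 5 were lower (H2-Q7, Erap1, and Psmb8, Psmb9 and Psmb10, which the proteasome list also holds) and 0 higher. Immediate early genes also lay within the random lists (median −0.044, percentile 69.3), with Jun and Nfkbia higher among 9. Neither was within cells called G1, with Jun at 29.1 and 26.4 CPM and Nfkbia at 66.5 and 81.0 CPM. Cd8a was at 364 and 248 CPM.

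**Figure D4:**
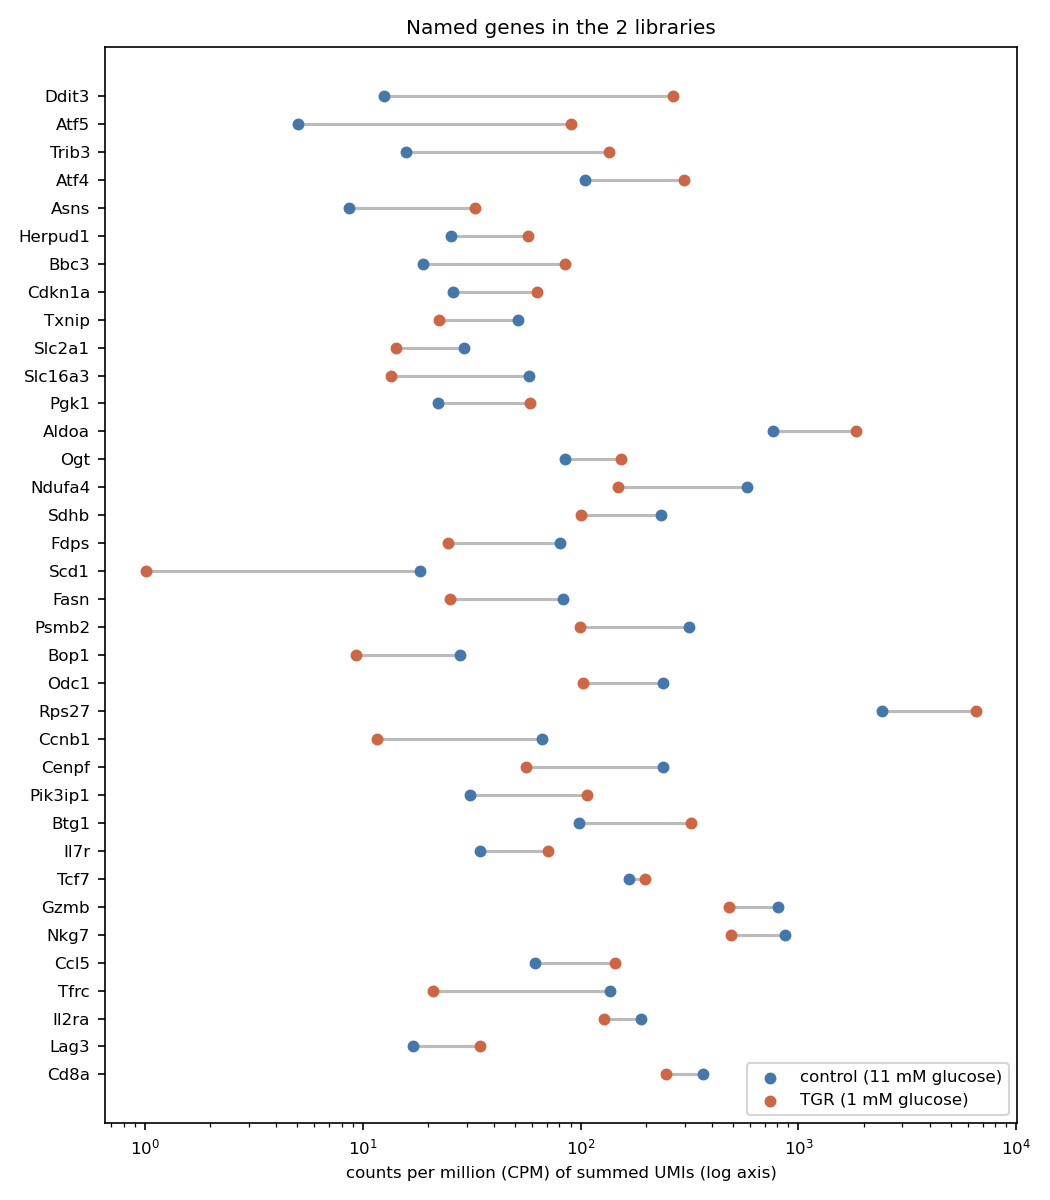
Points give the CPM of named genes in the control (blue) and TGR (orange) libraries on a log x axis, joined by a line per gene. Ddit3 spans 12.6 to 267 CPM and Scd1 18.3 to 1.02 CPM, while Tcf7 lies at 166 and 198 CPM.

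Cell identity was examined by clustering both libraries together. Of 6 clusters, 5 were CD8 T-like and held 99.1% of control cells and 100% of TGR cells. The remaining cluster of 27 control cells (0.863%, exact interval 0.570 to 1.25) was left unnamed. It held 0 of 2546 TGR cells, with an upper counting limit of 0.145%. This does not bound the share of similar TGR cells, which could lie in clusters formed mainly by TGR cells. The CD8 T-like clusters were nearly split by library, with 106 control and 1366 TGR cells in the most mixed, so their sizes were not compared. No cluster was named for B cells, myeloid cells or another cell type. The rule made such a name unlikely or impossible, since each cluster had 8 CD8 T cell markers detected. Another class would have needed more than 8 enriched markers. The CD4 T, gamma-delta T, mast cell or basophil, erythroid and platelet lists hold no more than 8, so these could not be named. The CD8 T cell list also holds general T cell genes such as Cd3e, so the name CD8 T-like does not by itself tell CD8 from other T cells. In the 5 CD8 T-like clusters at most 1 marker of another class was enriched.

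The differences were then recomputed within 3 phases and 3 bands of UMIs per cell. Lists for ATF4 targets, FOXO targets, type I interferon, activation receptors, ribosomal proteins, oxidative phosphorylation, the TCA cycle, cholesterol synthesis, the proteasome and histones kept their side of the random lists in 6 of 6 subsets. Fatty acid synthesis and p53 targets did so in 5 of 6. MYC targets, autophagy and naive and memory lists did so in 4 of 6, and the hexosamine list in 3 of 6. The G2/M and S phase lists did so in each of the 3 bands, and were not read within phases because the phase calls use their genes. Some lists within the random lists over all kept cells stood above them in subsets: HIF1 targets in G1, S and the lowest band, endoplasmic reticulum genes in G1, S and the highest band, cytokines in the lower bands, aminoacyl-tRNA synthetases in G1 and immediate early genes in the lowest band. Ddit3 was between 204 and 298 CPM in every TGR subset and between 8.29 and 14.7 CPM in every control subset. Of 108 scored named genes at least 1.5-fold apart over all kept cells, 96 stayed so in the same direction within G1, 105 within S and 107 within G2/M, and 96, 103 and 107 within the bands from lowest to highest. Many of these genes were named for large ratios in the same cells, so these numbers were partly built in. Within G1 the genes under 1.5-fold in the same direction were Prps1, Ogt, Acaa2, Bop1, Gzmb, Ccl5, Nfkbia, Slc19a1 and Il7r. The direction turned within G1 for Cdkn1a, Jun and Egln3 (22.8 and 24.0 CPM), and within the lowest UMI band for mt-Nd6 (45 and 16 UMIs).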

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

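This group of barcodes was described only after the filter's effect had been seen. Barcodes left out of the comparisons for 10% or more mitochondrial UMIs numbered 209 of 3336 in the control library (6.26%, exact interval 5.47 to 7.14) and 2 of 2548 in the TGR library (0.0785%, 0.0095 to 0.283). They drew attention because the comparisons left them out, with Gzmb and Cd8a above the level of the kept control cells. Gzmb was at 4089 CPM in the removed and 803 CPM in the kept control barcodes, Cd8a at 1346 and 364 CPM and the nuclear transcript Malat1 at 9494 and 2219 CPM. Ptprc (1539 and 333 CPM), Cd3e (257 and 122 CPM) and mt-Co1 (26601 and 5065 CPM) were also higher in them, while Actb (1895 and 4615 CPM) and Eef1a1 (5258 and 7425 CPM) were lower. Their median was 1545 UMIs, with 17.3% mitochondrial and 14.5% ribosomal protein UMIs. Ddit3 was at 16.1 CPM in them against 12.6 CPM in the kept cells, from 6 UMIs. No explanation was tested.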

How the results depend on the processing

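The alternatives were all chosen before the data were examined. No paired analysis was possible because each condition has 1 library. Counts of genes at least 2-fold higher (221) and lower (525) moved by over 1.5 times under 3 settings. Without ribosomal protein and mitochondrial genes in the totals they were 405 and 235, which follows from the changed totals. Without a filter on low values (14990 genes) 859 were higher and 745 lower, so higher genes became 53.6% of those counted against 29.6%. With a minimum of 50 CPM (2307 genes) 73 were higher and 316 lower. The cause was not tested for either filter. In the other settings higher genes numbered 197 to 249 and lower genes 434 to 561. The number of lists outside the random range stayed within 1.5 times in all 11 settings. For the TMM, DESeq2 and changed-total settings this was in effect fixed in advance. They shift all log2 ratios by nearly the same amount and leave the scored genes and expression bins unchanged. At 50 CPM the medians of the autophagy and lysosome list (−0.018) and the type I interferon list (−0.049) turned negative. Of the other list values, 381 were counted as unchanged, 9 gained a call and 4 lost it. The 381 include the list that holds Txnip, which had no call to keep. They also include values under the TMM, DESeq2 and changed-total settings, where calls could hardly change. No named gene that differed at least 1.5-fold turned direction under these settings, which do not include the recomputation within phases and UMI bands. Over the settings, 1412 log2 ratios of named genes stayed within the counting interval of the main value and 337 moved outside it. The share of cells in S or G2/M was 95.01% control and 50.1% TGR in unthinned cells and 87.9% and 43.3% over all deposited barcodes, against 91.7% and 47.4%. The control share in non-CD8 T clusters was 0% over all deposited barcodes against 0.863%, where a cluster of 21 control cells led by Fcer1g, Ifitm1 and Gzmc was still present but had 2 enriched markers of another class, under the 3 needed, and so was called CD8 T-like. It was also 0% with libraries clustered separately, where Fcer1g and Ifitm1 led a larger cluster of 458 control cells called CD8 T-like. With cell cycle genes left out it was 0% and no cluster was led by Fcer1g. In neither setting does 0% mean that the unnamed cells were absent, and where they fell was not traced. Depth limits genes with few UMIs: 3 counts correspond to 0.204 CPM in control and 0.152 CPM in TGR.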

Other observations

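Tests in this part chosen only after the results were seen are those on depth and library preparation for ATF4 targets, those on the ribosomal protein share, and those on non-coding genes. The tests by TGR cluster, on coding snoRNA hosts and on 5′ TOP messages were set before their results were seen. Genes outside the naming rule here were chosen after their values were seen.

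Non-coding transcripts stood apart in the TGR library. Of 76 scored non-coding genes that host no small nucleolar RNA (snoRNA), 37 were at least 1.5-fold higher and 6 lower, with a median log2 ratio of 0.54, against −0.16 over 6552 protein-coding genes. The abundant nuclear transcripts Malat1 (2219 and 5738 CPM) and Neat1 (24.6 and 89.1 CPM) were among those higher. The metallothionein gene Mt1 was at 182 and 432 CPM, beside Mt2 at 38.4 and 246 CPM.

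Cox6a2 was detected in 690 of 2546 TGR cells (27.1%, exact interval 25.4 to 28.9) and 2 of 3127 control cells (0.064%). After thinning, the numbers were 205 of 2546 (8.05%) and 0 of 3036, which allows up to 0.121% of control cells with a UMI. These libraries hold no named cell type to give a background share. The top 1% of TGR cells (26 cells) held 12.2% of its UMIs, and no cell had more than 10. The 5 annotated genes with UMIs within 50 kb summed to 9.78 CPM in control and 8.88 CPM in TGR.

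The 27 unnamed control cells expressed Fcer1g (478 CPM against 2.13 CPM in other control cells), Gzmc (251 and 0.549 CPM), Ifitm1 (1049 and 43.0 CPM) and Gzmb (2249 and 787 CPM). Cd3g was similar (522 and 582 CPM), while Cd8a (75.4 and 367 CPM) and Cd8b1 (132 and 549 CPM) were lower. Some genes often found in natural killer cells were also higher, each from few of the 27 cells: Tyrobp (81.7 and 1.37 CPM, 6 cells), Gzma (245 and 6.31 CPM, 4 cells) and Klre1 (56.5 and 2.40 CPM, 7 cells). Klrb1c had a UMI in 1 of them, and Ncr1 had 0 UMIs in them and in the other control cells.

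The higher ATF4 target list was weighed against 3 explanations. A difference in depth would have brought it within the random lists in some shared band of UMIs per cell. The lowest percentile over the 3 bands was 100, with a lowest median of 0.58. The bands were wide (1274 to 3949, 3949 to 6355 and 6355 to 36429 UMIs). They held 1510, 964 and 653 control and 380, 926 and 1240 TGR cells. Depth was thus only roughly matched and may still differ between the libraries within a band. A rise confined to some of the 5 clusters of the TGR library would have left the others within the random lists. The lowest percentile was 98.15, in a cluster of 508 cells with a median of 0.14 and Ddit3 at 231 CPM. The rise was uneven, with medians from 0.64 to 1.08 in the other clusters. UMIs were summed per cluster, so a minority of high cells spread over all clusters could not be excluded. A difference between cultures or library preparations other than glucose cannot be told apart from the treatment, because there was 1 library per condition. An effect of 1 mM glucose may therefore be one hypothesis among others that remain open.

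The larger ribosomal protein share in TGR cells was weighed next. If depth were the cause, the shares would differ by 5 points or less in some band of UMIs per cell. TGR was above control by at least 9.02 percentage points in each of the same 3 wide bands, which match depth only roughly. Cell cycle mix would likewise close the gap within phases, where the smallest difference was 7.44 points, in G1. Whether ribosomal protein messages were gained or other messages lost cannot be told apart: UMIs per cell were 2.05-fold higher for ribosomal protein genes and 1.37-fold higher for genes outside them and the mitochondrial genome, but UMIs per cell also depend on capture and sequencing. An effect of glucose restriction was not separable from a library effect.

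The third pattern was the high level of Snhg12, Snhg6 and other non-coding snoRNA hosts in TGR, 6 of 8 at least 1.5-fold higher with a median of 1.94. A rise of all snoRNA hosts would need the 132 coding hosts outside ribosomal proteins to share it, but their median of −0.25 stood at percentile 13.9 of random lists, with 34 lower and 6 higher. A rise of non-coding transcripts as a whole goes with the other non-coding genes (median 0.54, percentile 100), yet not at the size seen in the hosts, whose median stood at percentile 100 among sets of those genes and at 99.8 without Snhg12 and Snhg6. Unlike the random lists, these sets were not matched on expression. Messages with a 5′ terminal oligopyrimidine tract (5′ TOP), a class known to include such hosts, were also above random lists (24 genes outside ribosomal proteins, median 0.23, percentile 99.76), far below the hosts' 1.94. An effect of glucose restriction and a library effect both remain open.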
